A study of Mus musculus with 6 samples.

How the data were processed

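RNA-seq was performed on total RNA from the renal cortex of C57BL/6 mice, an inbred laboratory strain. The series holds 3 sham samples and 3 samples (IR24h) taken 24 h after reperfusion that followed a 30 min clamp of both renal pedicles, the stalks that carry the vessels of the kidney. RNA was extracted with an AMBION kit and libraries followed a TruSeq RNA preparation guide, per the labels. Whether the libraries kept the strand of the RNA is not given in the sources used here, nor whether each library came from a separate mouse. P-values of the comparison of IR24h with sham thus measure the spread between these libraries. Per the submitters' processing notes, the authors used CASAVA 1.8 and TopHat2 2.0.6, and both mm10 and GRCh38 are named as genome builds. The gene identifiers are mouse identifiers. The read counter and the annotation are not given in the sources used here.

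Per the file headers, the authors gave raw counts of reads per gene for each of the 6 libraries, which were whole numbers and served as the main measurement. The authors also gave FPKM values, counts scaled by gene length and library total, which were not compared between the groups. They were used here only to recover, from count and FPKM, the gene length and library total behind each value, on which the test of genes of the same implied length and the estimate of reads outside the listed genes rest. Of the 22040 genes listed, 83 had no value in the sham libraries and were left out, which left 21957. Of the genes listed, 22010 were matched by identifier to GENCODE M21 (GRCm38, the same assembly as mm10), which gave all coordinates. In the table, 26 symbols had turned into dates and were restored from the identifier, and 31 symbols were shared by several identifiers, which were kept as separate genes.

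The sham and the IR24h values differed in how they had been made. The gene length implied by count and FPKM could be compared between the groups for 12806 genes with at least 5 counts. It differed by more than 0.01 on the log2 scale for 1681 of them, 13.1%, being shorter in the IR24h libraries for 1482 and longer for 199. Within groups it differed for 0 genes. The library total behind the FPKM values exceeded the sum of the listed counts by 7.91 to 9.74% in the sham libraries and by at most 4.03e-06% in the IR24h libraries. The processing is thus confounded with the groups, and no test here can part the 2.

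Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's expression filter, which left 13609. Libraries were scaled by the trimmed mean of M-values (TMM), and IR24h was compared with sham by edgeR's quasi-likelihood test, 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values, counts scaled to a common library size, use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.394. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

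Totals were 14339985, 17061844 and 15952851 counts in sham libraries 1, 2 and 3 and 12877853, 16000942 and 13298618 in IR24h libraries 1, 2 and 3. On data simulated at the depth and spread of these libraries, the test called 12 of 69 genes changed 4-fold (17.4%), all in the right direction. It called 0 of 69 genes changed 2-fold and 0 of 62 changed 1.5-fold, with 1 false call among 13480 genes. Few genes were changed in the simulation, and adjustment over all genes is stricter where few genes change. In the real data 2214 genes were called, so the simulation may understate what was detectable there. Where all libraries of a group held 0 counts, a bound is given against 3 counts over the group, and 95% counting intervals are exact. These cover counting error only, since reads from PCR are not independent molecules.

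Before the data were examined, 27 gene lists with 538 different genes were fixed. They cover the handling of oxidised RNA, RNA exonucleases, interferon-stimulated genes, tubular injury, the nephron segments and other cell types of the cortex, inflammation, redox and energy metabolism, stress, cell death, cell division and ribosome formation. A last list holds markers of neighbouring tissue (adrenal, fat, blood and urothelium). Lists with at least 5 tested members, 26 of them, were tested with camera on voom values at a preset correlation between genes of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated for each list, camera on ranks, and fry, which asks whether the genes of a list move on balance to one side.

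The named genes were also fixed by a rule. It takes Isg20, Havcr1 and Lcn2; the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups; and, for each list, called members with at least 5 CPM in the higher group, the 2 with the largest change in the direction of the majority and the 1 with the largest change the other way, or, where none passed, the member with the highest mean. For the lists on oxidised RNA and RNA exonucleases it takes up to 6 called members without a minimum. The rule named 68 genes, some of which are not reported here. A named gene whose counts may be shared with another is described as such where the share was 27.4% or more. The share is that of 50-base stretches that its transcripts share with another gene, or of exon bases that overlap a gene on the opposite strand. Smaller shares are not described further, among them overlaps of 19.1% for Gadd45a and shared stretches of 19.0% for Fbl and 16.1% for Ndufs3.

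Alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, no count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, removal of mitochondrial genes, and leaving out each library in turn. Added after seeing the data were a test on genes of the same implied length, a test without raised stretches of neighbouring genes, removal of a gene length and GC trend, and a test without IR24h libraries 1 and 3, which have the highest mitochondrial share. That last test leaves 1 IR24h library, which is assumed to vary like the sham libraries. A raised stretch was a run of neighbouring tested genes in which at least 3 of 5 consecutive genes were called with a log2 fold change of at least 3.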

Results

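Gene expression was measured by RNA-seq in the renal cortex of mice after sham surgery (3 libraries) and 24 h after reperfusion of kidneys whose pedicles had been clamped for 30 min (IR24h, 3 libraries). This procedure is a model of acute kidney injury. Sham libraries held 14339985 to 17061844 counts and IR24h libraries 12877853 to 16000942. Genes of the mitochondrial genome took 13.8% ± 0.571 (SD, n = 3) of the counts in sham libraries and 48.1% ± 21.4 in IR24h libraries, with 68.9, 26.2 and 49.2% in IR24h libraries 1, 2 and 3. Counts from all other genes were 12455991, 14639820 and 13713058 in sham libraries 1 to 3 and 4008617, 11806407 and 6756322 in IR24h libraries 1 to 3. Across genes, log2 CPM of the sham libraries correlated at r = 0.974 to 0.983. IR24h library 2 stood apart from IR24h libraries 1 and 3 (r = 0.759 and 0.773), which correlated with each other at 0.898. With the sham libraries IR24h library 2 correlated at 0.812 to 0.830, above its values with IR24h 1 and 3. IR24h libraries 1 and 3 correlated with sham at 0.680 to 0.749. The library scaling factors were 1.22, 1.22 and 1.16 in sham and 0.547, 1.22 and 0.861 in IR24h libraries 1 to 3. The series asks what RNA oxidation contributes to acute kidney injury, with ISG20, an RNA exonuclease, named as the enzyme that degrades oxidised RNA. The comparison of IR24h with sham gives the genes that differ after ischemia/reperfusion.

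Of the tested genes of tubular injury and of inflammatory signals, 23 of 24 and 15 of 18 were higher in the injured cortex. Those 18 were the ones of 28 inflammatory signal genes that passed the expression filter. Of the tested proximal tubule genes, 20 of 32 were lower and 1 higher. As lists, tubular injury and proximal tubule were not called with an estimated correlation (adjusted p = 0.125 and 0.228). Havcr1, which encodes the injury marker KIM-1, rose from 1.2 ± 0.493 CPM (SD, n = 3) in sham to 1426 ± 860 CPM in IR24h. Lcn2, which encodes the secreted iron-carrier protein NGAL, rose from 0.754 ± 0.349 to 283 ± 40.1 CPM. Among lower genes, Inmt, a methyltransferase, fell from 965 ± 53.6 to 18.8 ± 9.54 CPM. Isg20 rose from 1.8 ± 0.472 to 12.4 ± 7.17 CPM. Of 13609 genes tested, 1177 were higher and 1037 lower in IR24h (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 2101 of these differed at least 2-fold. At an unadjusted p under 0.05 the count was 4645. The higher share of the called genes was 53.2%, and it was 39.4% (398 higher, 611 lower) with library size as the only scaling, where the median log2 fold change of all genes was −0.39 against 0.05 with TMM. The counts depended on the libraries used. Without sham 1, 2 or 3 there were 283, 246 or 292 higher and 237, 212 or 196 lower genes. Without IR24h 1 or 3 there were 842 or 813 higher and 709 or 749 lower genes. Without IR24h 2 there were 3297 higher and 3382 lower genes, which included 1175 of the 1177 higher and each of the 1037 lower genes.

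Isg20 (ENSMUSG00000039236) lies on chromosome 7 from 78913424 to 78920396 (GRCm38). Its log2 fold change was 2.78 ± 0.52 (SE; adjusted p = 0.0146), with 2.34, 1.54 and 1.51 CPM in sham libraries 1 to 3 and 19.7, 5.42 and 12.1 CPM in IR24h libraries 1 to 3. The counts behind these values were 41, 32 and 28 in sham and 139, 106 and 139 in IR24h. An exact permutation test of the log2 CPM, 2-sided over the 20 assignments, gave p = 0.1, the smallest that 3 against 3 libraries allow. The call was lost without sham 1, 2 or 3 (adjusted p = 0.0564, 0.0800 and 0.0779), and the log2 fold change was 1.61 (adjusted p = 0.0157) with IR24h 2 as the only injured library. Havcr1 (ENSMUSG00000040405; chromosome 11, 46735080 to 46779578) changed by 10.21 ± 0.75 (adjusted p = 7.97e-04) and Lcn2 (ENSMUSG00000026822; chromosome 2, 32384633 to 32388252) by 8.55 ± 0.48 (adjusted p = 6.67e-04).

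**Figure D1:**
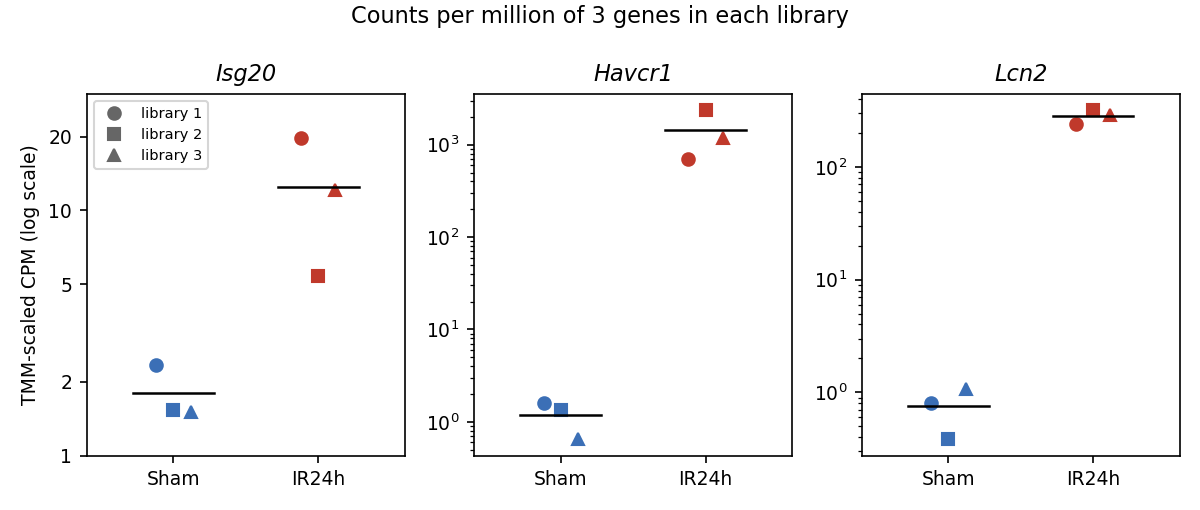
TMM-scaled CPM (log scale) of Isg20, Havcr1 and Lcn2 in each sham (blue) and IR24h (red) library; marker shapes stand for library numbers and horizontal lines for group means. Each IR24h value lies above each sham value, and for Isg20 IR24h library 2 is the lowest of the injured libraries at 5.42 CPM.

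The genes with the highest log2 fold changes included several with next to no sham counts. Fosl1, a subunit of the AP-1 transcription factor, had 0 counts in all sham libraries and was at least 555-fold higher in IR24h, although 57.2% of its exon bases overlap Ccdc85b on the opposite strand (−0.57 ± 0.35, adjusted p = 0.279), a gene named for its position after its values were seen. Hist2h2aa2, a histone gene that shares 100% of its 50-base stretches with another gene, was at least 261-fold higher, and Sprr2f, a cornified envelope gene in a raised stretch of neighbours on chromosome 3, at least 244-fold. Krt20, a keratin, rose from 0.106 ± 0.144 to 142 ± 108 CPM. The chemokine gene Cxcl2 had 3 counts over the sham libraries and a pooled ratio of 555 (95% counting interval 189 to 2695). Its call was lost with limma-voom (adjusted p = 0.0684) and without sham 1, 2 or 3 (adjusted p = 0.0520, 0.0534 and 0.0540), and its log2 fold change was 9.46 in the full set and 5.50 with IR24h 2 alone. Sprr1a rose from 0.395 ± 0.304 to 152 ± 74.4 CPM and lies in the same stretch as Sprr2f. The lowest log2 fold changes included those of Pde6a (−7.53 ± 0.73), a phosphodiesterase gene whose implied length differed between the groups, Fam221b (−7.33 ± 0.91), the lectin gene Clec2h (−5.71 ± 0.41), Inmt (−5.69 ± 0.51), the phosphate transporter Slc34a3 (−5.64 ± 0.44), the carboxylesterase Ces1g (−5.59 ± 1.12) and the organic anion transporter Slco1a1 (−4.94 ± 0.73). Ces1g was no longer called without sham 1, 2 or 3 or IR24h 1 (adjusted p = 0.0534 to 0.0729), and without IR24h 2 its value was −9.64 and that of Pde6a −11.49.

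RNA exonucleases showed a few changed members. Of 28 tested, 3 rose (Isg20, Exosc8 and Aen), 1 fell (Eri2) and 24 were not called. Adjusted over the list alone, 4 were higher and 1 lower. Aen lies close beside Isg20 on chromosome 7, from 78895854 to 78911209, so the rises of these genes may not be independent. Neither lay in a raised stretch. Exosc8, a subunit of the RNA exosome, rose from 5.17 ± 0.340 to 21.4 ± 11.7 CPM (log2 fold change 2.04 ± 0.49, adjusted p = 0.0308), and Aen, a nuclease induced by p53, from 17.8 ± 1.04 to 58.1 ± 24.5 CPM (1.7 ± 0.34, adjusted p = 0.0167). Eri2 fell from 28.8 ± 13.7 to 6.68 ± 1.11 CPM (−2.11 ± 0.39, adjusted p = 0.0137); 27.4% of its exon bases overlap Acsm3 on the opposite strand, which also fell (−1.77 ± 0.34) and was named in the same way. Among 17 genes for the handling of oxidised RNA, 2 rose, both RNA-binding proteins, and 15 were not called, with the same 2 adjusted over the list alone. Pcbp2 rose from 99.2 ± 7.38 to 319 ± 128 CPM (1.69 ± 0.35), with a differing implied length and 30.2% of its exon bases opposite Map3k12, and Hnrnpd rose from 32.9 ± 2.72 to 61.5 ± 6.54 CPM (0.90 ± 0.23, adjusted p = 0.0365). Neither list was called by camera (adjusted p = 0.0868 and 0.198; 0.341 and 0.436 with an estimated correlation), while fry, which asks about the list alone and not against other genes, called both as higher (adjusted p = 0.00282 and 0.0165). None of the 28 tested members of the interferon-stimulated list was called by edgeR, 0 higher and 0 lower also adjusted over the list alone. The list does not hold Isg20, by its name an interferon-stimulated gene, which was called higher. Its members had a median log2 fold change of −0.93 and the list a camera adjusted p of 0.0678 (0.775 with an estimated correlation). Ifit3, the most abundant member, had 95.9 ± 120 CPM in sham and 56.4 ± 37.1 CPM in IR24h (adjusted p = 0.612), and 51.2% of its 50-base stretches are shared with Ifit3b. Sham library 1 set the sham mean, with 235 CPM of Ifit3 against 28.5 and 24.7 CPM in sham 2 and 3 and 71.3, 14.1 and 83.7 CPM in IR24h 1 to 3. Of the 28 genes, 23 were highest in sham 1, and without it the camera adjusted p of the list was 0.580. It was 0.0134 and 0.00111 without sham 2 or 3, where sham 1 weighs more. Without IR24h 1, 2 or 3 it was 0.0470, 0.876 and 0.0142, each time in the lower direction. The list was called as lower with upper-quartile scaling (0.0454), without a count filter (0.0260), with the replicate block (0.0288), by camera on ranks (0.0409) and with IR24h 2 alone (0.0116), and not by fry (0.521). The calls of Pcbp2, Hnrnpd, Exosc8 and Aen were lost without any 1 of the sham libraries (adjusted p = 0.0800 to 0.194) and with library size as the only scaling (0.0856 to 0.527), where Hnrnpd changed by 0.49 and Aen by 1.12. That of Exosc8 was also lost without IR24h 1 or 3 (0.0831 and 0.0830), that of Hnrnpd without IR24h 3 (0.0617) or a count filter (0.0615) and that of Eri2 without sham 3 (0.0575). With the replicate block Hnrnpd and Exosc8 were not called (0.0936 and 0.0557), nor Exosc8 with limma-voom (0.0728). With IR24h 2 alone the log2 fold change of Pcbp2 was 0.95 and that of Exosc8 0.63 (adjusted p = 0.0907).

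Tubular injury genes rose nearly throughout. Of 24 tested, 23 were higher, 0 lower and 1 not called, with 24 higher adjusted over the list alone and a median log2 fold change of 3.95, and the list was called by camera (adjusted p = 4.87e-20; adjusted p = 0.125 with an estimated correlation). It holds Havcr1, Lcn2, Krt20, Fosl1 and both Sprr genes named above. Of 28 inflammatory signal genes, 18 passed the expression filter. Members low in both groups are thus missing, and those near 0 in sham could pass only through the IR24h libraries. Of the 18, 15 rose and 3 were not called, with 17 higher adjusted over the list alone and a median of 4.17. Camera called the list with the preset and with an estimated correlation (adjusted p = 1.24e-10 and adjusted p = 0.0484). Ptgs2, which encodes the prostaglandin-forming enzyme cyclooxygenase-2, rose from 0.146 ± 0.0912 to 44.3 ± 50.8 CPM (8.20 ± 1.47, adjusted p = 0.0126). Mesenchyme and matrix genes were higher for 13 of 15 with 2 not called (15 adjusted over the list alone; median 2.75; camera adjusted p = 3.64e-08, adjusted p = 0.334 with an estimated correlation). Postn, a matrix protein, rose from 0.401 ± 0.104 to 13.4 ± 9.33 CPM (5.02 ± 0.62). The call of Ptgs2 was lost with limma-voom (adjusted p = 0.10) and without sham 1, 2 or 3 (adjusted p = 0.0568, 0.0642 and 0.0690). With IR24h 2 alone Ptgs2 changed by 4.18.

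Leukocyte markers moved in part. Of 18 macrophage and monocyte genes, 6 rose and 12 were not called, the same adjusted over the list alone (median 0.48; camera adjusted p = 0.0188, adjusted p = 0.508 with an estimated correlation). Itgam, an integrin subunit of myeloid cells, rose from 0.387 ± 0.0113 to 6.93 ± 4.50 CPM, with 66.3% of its 50-base stretches shared with Gm49368, and the scavenger receptor Msr1 from 0.378 ± 0.183 to 5.61 ± 2.48 CPM. Only 5 of 17 neutrophil genes passed the expression filter. Of these, 3 rose, 1 fell and 1 was not called, the same adjusted over the list alone. Their median was 2.18 (camera adjusted p = 0.208, adjusted p = 0.464 with an estimated correlation). Of the 5, 2 lie in a raised stretch of neighbours, S100a9 and S100a8, the latter named after its values were seen. S100a9, a calcium-binding protein of neutrophils, rose from 0.106 ± 0.00915 to 5.03 ± 3.4 CPM. Hdc, histidine decarboxylase, fell from 6.01 ± 0.610 to 1.41 ± 0.708 CPM. In sham Hdc stood far above S100a9, and which cells its counts came from was not tested, so its fall need not concern neutrophils. Of 19 lymphocyte genes, 3 were tested and 0 called, too few for a set test; Lck had 1.26 ± 0.508 CPM in sham and 1.52 ± 0.777 CPM in IR24h (adjusted p = 0.801). The macrophage list was not called without IR24h 3, with IR24h 2 alone or by fry (adjusted p = 0.182, 0.394 and 0.0820). The neutrophil list was called as higher without sham 1, 2 or 3 or IR24h 1 (adjusted p = 0.0119, 0.0211, 0.0207 and 0.0470), and so it was with library size as the only scaling (0.0478) and without a count filter (0.00543). Itgam and Hdc were not called without sham 1, 2 or 3 (adjusted p = 0.0529 to 0.0945), nor Hdc without IR24h 3 (0.0573). Itgam changed by 4.12 ± 0.68 in the full set and by 2.43 with IR24h 2 alone.

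**Figure D2:**
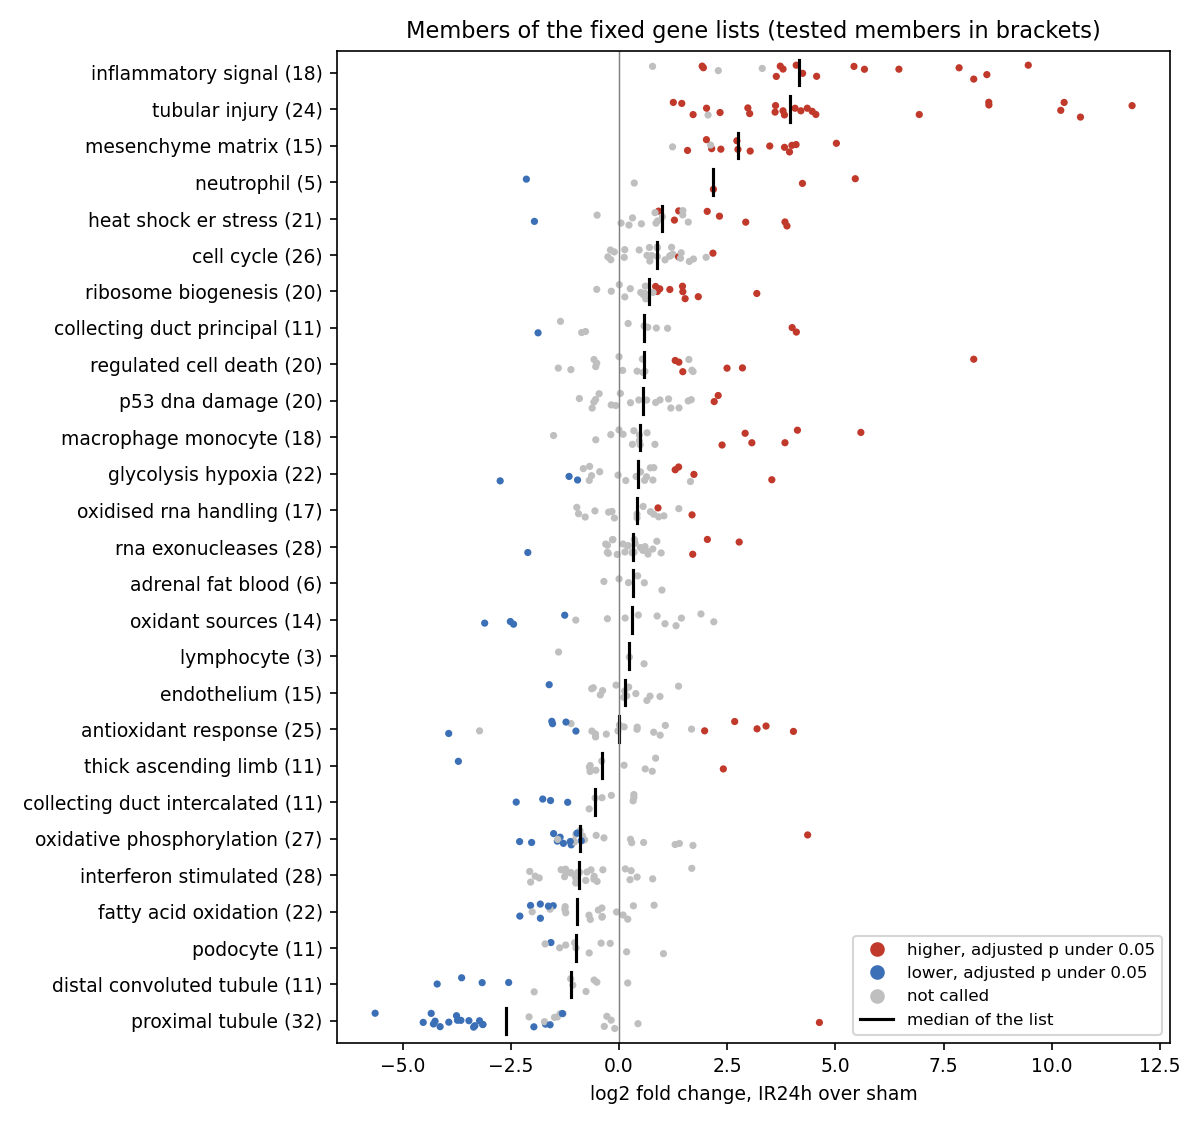
Log2 fold change (IR24h over sham) of each tested member of the fixed gene lists, 1 point per gene, with black bars at the list medians; red and blue points are members called higher and lower. The medians run from −2.61 for the proximal tubule to 4.17 for inflammatory signals. No member of the interferon-stimulated list, which does not hold Isg20, is called.

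Proximal tubule genes fell in part. Of 32 tested, 20 were lower, 1 higher and 11 not called (23 lower and 1 higher adjusted over the list alone), with a median of −2.61 (camera adjusted p = 4.39e-12; adjusted p = 0.228 with an estimated correlation). Slc34a3 fell from 114 ± 8.79 to 2.24 ± 1.09 CPM and Gatm, an enzyme of creatine synthesis, from 890 ± 198 to 38.4 ± 38.8 CPM. The higher member was the urate transporter Slc22a12, with 25.4 ± 2.74 CPM in sham and 629 ± 160 CPM in IR24h (4.63 ± 0.32). It lies in a raised stretch on chromosome 19 and has 30.1% of its exon bases opposite Nrxn2. Sham reads of such stretches may have been left out, so whether its expression rose stays open. Of 11 distal convoluted tubule genes 4 fell and 7 were not called (6 adjusted over the list alone; median −1.12; camera adjusted p = 5.04e-04, adjusted p = 0.345 with an estimated correlation). Pvalb, parvalbumin, fell from 17.7 ± 2.29 to 1.47 ± 0.793 CPM, and the sodium/calcium exchanger Slc8a1, whose implied length differed, from 107 ± 18.9 to 5.64 ± 6.60 CPM. The thick ascending limb list had 1 higher, 1 lower and 9 not called members, the same adjusted over the list alone (median −0.40; camera adjusted p = 0.338, adjusted p = 0.794 with an estimated correlation). In it Egf, the epidermal growth factor gene, fell from 1290.2 ± 47.2 to 98.4 ± 38.1 CPM (−3.71 ± 0.40), and the claudin Cldn19 rose from 17.8 ± 4.42 to 94.6 ± 50.9 CPM (2.41 ± 0.49). Slc8a1 and Cldn19 were not called without sham 1, 2 or 3 (adjusted p = 0.0577 to 0.0927) or without IR24h 1 (0.0533 and 0.0529), nor Cldn19 without IR24h 3 (0.0528). Cldn19 changed by 1.08 with IR24h 2 alone. With IR24h 2 alone the thick ascending limb list was called as lower at the preset correlation (adjusted p = 0.00175), against an estimated correlation of 0.535 in the full set.

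In the collecting duct, intercalated cell genes had 4 lower, 0 higher and 7 not called members of 11, the same adjusted over the list alone (median −0.55; camera adjusted p = 0.0374, adjusted p = 0.448 with an estimated correlation). Slc26a4, the anion exchanger pendrin, fell from 120 ± 8.37 to 22.9 ± 16.4 CPM (−2.38 ± 0.49), and the oxoglutarate receptor Oxgr1 from 33.4 ± 1.51 to 9.74 ± 6.78 CPM (−1.76 ± 0.47). Principal cell genes went both ways, with 2 higher, 1 lower and 8 not called of 11, and 2 higher and 3 lower adjusted over the list alone (median 0.58 and mean 0.61, against a camera test in the lower direction at adjusted p = 0.95). The water channel Aqp4 rose from 2.19 ± 1.08 to 37.6 ± 41 CPM (4.10 ± 0.88) and the transcription factor Elf5 from 0.324 ± 0.189 to 5.36 ± 5.73 CPM (4.0 ± 0.92), both with a differing implied length, while Aqp3 fell from 112 ± 5.25 to 30.7 ± 17.3 CPM. Leaving out any 1 sham library ended each of these 5 calls (adjusted p = 0.0710 to 0.134). The same held for leaving out IR24h 3 for Elf5, Slc26a4 and Oxgr1 (0.0535, 0.0611 and 0.0864) and IR24h 1 for Oxgr1 (0.113). Aqp4 and Elf5 changed by 2.67 and 2.62 without IR24h 3. With IR24h 2 alone the changes were 2.20 for Aqp4, −1.51 for Slc26a4 and −0.92 for Oxgr1, and the intercalated list was not called without IR24h 2 (adjusted p = 0.213). On genes of the same implied length and with a length and GC trend removed it was not called either (0.0633 and 0.0559). With library size as the only scaling Elf5, Aqp3, Slc26a4 and Oxgr1 were not called (0.0508, 0.0508, 0.0651 and 0.105), nor Elf5 with limma-voom (0.0517).

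Among podocyte genes 1 of 11 fell, 10 were not called and 0 rose, the same adjusted over the list alone (median −1.0; camera adjusted p = 0.0475, adjusted p = 0.464 with an estimated correlation). Endothelial genes had 1 lower, 0 higher and 14 not called of 15, the same adjusted over the list alone, with a median of 0.13 and a mean of 0.07 against a camera test in the lower direction (adjusted p = 0.374, adjusted p = 0.874 with an estimated correlation). Kdr, a receptor of vascular endothelial growth factor, fell from 59.8 ± 10.2 to 19.6 ± 5.59 CPM (−1.61 ± 0.30, adjusted p = 0.0146). With IR24h 2 alone the endothelial list was called as lower at the preset correlation (adjusted p = 7.71e-07), against an estimated correlation of 0.791 in the full set, and the podocyte list was not called (adjusted p = 0.121). The podocyte list was also not called without sham 2, IR24h 1 or IR24h 3 (adjusted p = 0.0542, 0.0633 and 0.0737), with library size as the only scaling (0.0693) or by fry (0.0670). Kdr was not called without sham 1, 2 or 3 (adjusted p = 0.0723, 0.0785 and 0.0543).

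Genes of energy metabolism in mitochondria fell in part. Of 27 nuclear genes of oxidative phosphorylation, 10 were lower, 1 higher and 16 not called (13 lower and 3 higher adjusted over the list alone; median −0.90; camera adjusted p = 5.94e-04, adjusted p = 0.464 with an estimated correlation). Uqcrfs1 of complex III fell from 431 ± 33.9 to 87.6 ± 26.7 CPM and Cox5a of complex IV from 212 ± 25.1 to 52.2 ± 9.30 CPM. The higher member, Ndufs3 of complex I, had 3.12 ± 0.715 CPM in sham and 64.1 ± 21.1 CPM in IR24h. It lies in a raised stretch on chromosome 2. Sham reads of such stretches may have been left out, so whether its expression rose stays open. Of 22 fatty acid oxidation genes, 6 fell and 16 were not called, the same adjusted over the list alone (median −0.96; camera adjusted p = 5.04e-04, adjusted p = 0.464 with an estimated correlation), and Echs1, an enoyl-CoA hydratase, fell from 227 ± 9.78 to 46.3 ± 17.5 CPM. Acads, a short-chain acyl-CoA dehydrogenase, fell from 176 ± 43.1 to 42.7 ± 20.6 CPM. Glycolysis and hypoxia genes had 4 higher, 3 lower and 15 not called of 22, and 6 higher and 4 lower adjusted over the list alone (median 0.45; camera adjusted p = 0.488, adjusted p = 0.623 with an estimated correlation). Hexokinase 2 (Hk2) rose from 0.544 ± 0.286 to 6.33 ± 4.66 CPM, the glucose transporter Slc2a1 from 33.8 ± 5.55 to 112 ± 11.7 CPM, and the carbonic anhydrase Car9 fell from 15.8 ± 0.891 to 2.30 ± 0.918 CPM. Without sham 1, 2 or 3 Acads and Hk2 were not called (adjusted p = 0.0714 to 0.10), nor without IR24h 1 (0.0578 and 0.0619), nor Slc2a1 without sham 1 or 2 (0.0520 and 0.0546). Hk2 and Slc2a1 were not called with library size as the only scaling (0.0610 and 0.114), nor Hk2 with limma-voom (0.0583) or Acads with a length and GC trend removed (0.0507). The oxidative phosphorylation list was not called without IR24h 2 (adjusted p = 0.0526), nor fatty acid oxidation with IR24h 2 alone or by fry (adjusted p = 0.121 and 0.0562).

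Redox genes went both ways. Of 25 antioxidant genes, 5 rose, 5 fell and 15 were not called (7 and 7 adjusted over the list alone), with a median of 0.01 and a mean of 0.20 against a camera test in the lower direction (adjusted p = 0.95). The metallothioneins Mt1 and Mt2 rose from 64.6 ± 15.1 to 681 ± 449 CPM and from 16.5 ± 2.84 to 150 ± 68.4 CPM. For Mt2, 73.5% of the exon bases overlap Gm45774 on the opposite strand, which is not among the listed genes. The secreted glutathione peroxidase Gpx3 fell from 26256 ± 2269.6 to 1715 ± 1959.5 CPM. Of 14 genes for sources of oxidants, 4 fell and 10 were not called, with 2 higher and 4 lower adjusted over the list alone (median 0.29, against a mean of −0.09 and a camera test in the lower direction at adjusted p = 0.335, adjusted p = 0.464 with an estimated correlation), and fry called this list as lower (adjusted p = 0.00247). The NADPH oxidase Nox4 fell from 401 ± 27.4 to 46.5 ± 41.2 CPM and the hydroxyacid oxidase Hao2 from 244 ± 31.9 to 42.8 ± 11.4 CPM. Mt1, Gpx3 and Nox4 were not called without sham 1, 2 or 3 (adjusted p = 0.0518 to 0.0934), nor Gpx3 and Nox4 without IR24h 3 (0.0799 and 0.0605) or with library size as the only scaling (0.0544 and 0.0527), nor Gpx3 with a length and GC trend removed (0.0525). Mt1 changed by 3.4 ± 0.57 in the full set and by 1.96 with IR24h 2 alone.

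Stress and ribosome genes rose in part. Of 21 heat shock and endoplasmic reticulum stress genes, 8 rose, 1 fell and 12 were not called (14 higher and 1 lower adjusted over the list alone; median 1.0; camera adjusted p = 7.17e-05, adjusted p = 0.334 with an estimated correlation). The small heat shock protein Hspb1, with 48.8% of its 50-base stretches shared with a pseudogene, rose from 5.16 ± 1.33 to 76.1 ± 73.7 CPM and the transcription factor Atf3 from 0.910 ± 0.0866 to 13.1 ± 2.54 CPM, while Herpud1, of the endoplasmic reticulum, fell from 289 ± 52.7 to 74.3 ± 18.9 CPM. Of 20 ribosome formation genes, 9 rose and 11 were not called, the same adjusted over the list alone (median 0.70; camera adjusted p = 2.58e-05, adjusted p = 0.334 with an estimated correlation). Myc rose from 3.49 ± 1.68 to 31.7 ± 8.92 CPM, and Fbl, fibrillarin, from 10.8 ± 0.998 to 38.3 ± 6.49 CPM. Hspb1 was not called without sham 1, 2 or 3 (adjusted p = 0.0668 to 0.0782), Herpud1 without sham 3 (0.0517) and Fbl without sham 2 (0.0513) or with library size as the only scaling (0.0785). Hspb1 changed by 3.88 ± 0.74 in the full set and by 2.19 with IR24h 2 alone.

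Of 26 cell cycle genes, 2 rose and 24 were not called, the same adjusted over the list alone (median 0.88; camera adjusted p = 0.00433, adjusted p = 0.515 with an estimated correlation). Both were subunits of the helicase that opens DNA for replication: Mcm3 rose from 4.80 ± 1.09 to 21.6 ± 9.03 CPM and Mcm2 from 14.1 ± 1.59 to 36.4 ± 10.7 CPM. Of 20 p53 and DNA damage genes, 2 rose and 18 were not called, the same adjusted over the list alone (median 0.55; camera adjusted p = 0.141, adjusted p = 0.365 with an estimated correlation). These were Gadd45a, from 11.1 ± 0.303 to 50.9 ± 5.16 CPM, and Gadd45b, from 2.40 ± 0.524 to 11.8 ± 6.50 CPM (2.29 ± 0.52). Of 20 regulated cell death genes, 6 rose and 14 were not called, with 8 higher and 1 lower adjusted over the list alone (median 0.58; camera adjusted p = 0.126, adjusted p = 0.365 with an estimated correlation). Mlkl, the effector of necroptosis, rose from 1.28 ± 0.795 to 7.17 ± 2.21 CPM, and Ptgs2 is a member of this list too. The cell cycle list was not called without IR24h 3 or by fry (adjusted p = 0.0776 and 0.185). The p53 and cell death lists were called as higher by fry (0.0207 and 0.00624), the latter also with library size as the only scaling (0.0390) and with the replicate block (0.0470). Mcm2, Mcm3 and Gadd45b were not called without sham 1, 2 or 3 (adjusted p = 0.0520 to 0.12), Mlkl without sham 2 or 3 (0.103 and 0.0815), Mcm2 without IR24h 3 (0.0505) and Gadd45b without IR24h 1 or 3 (0.0687 and 0.0710). With library size as the only scaling Mcm3, Mcm2, Gadd45b and Mlkl were not called (0.0809, 0.250, 0.0644 and 0.0823), nor Mcm2 with the replicate block (0.0521) or Gadd45b with limma-voom (0.0587). With IR24h 2 alone Gadd45b changed by 0.95 (adjusted p = 0.0811).

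Markers of neighbouring tissue were not called: 0 of 6 tested genes were higher or lower, also adjusted over the list alone, with a median of 0.32 against a camera test in the lower direction (adjusted p = 0.95). Hba-a1, an alpha globin that shares 72.3% of its 50-base stretches with Hba-a2, had 13.5 ± 9.23 CPM in sham and 27.0 ± 17.7 CPM in IR24h (adjusted p = 0.351), and was called as higher without IR24h 2 (adjusted p = 0.0497). Some markers that did not pass the expression filter in enough libraries set IR24h 2 apart: the fat genes Adipoq, Plin1 and Cfd, named after their values were seen, had 313, 247 and 262 counts in IR24h 2, against 0, 0 and 22 in IR24h 1 and 3, 0 and 0 in IR24h 3.

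The shares of counts of the genes of the mitochondrial genome did not move as one. Of 13, 11 took a larger share of counts in each IR24h library than in each sham library, with ratios of mean shares between 2.68 and 14.7 among all but mt-Nd6, and mt-Nd3 overlapped between the groups; chance alone parts 3 against 3 values in 10% of cases. mt-Nd6, on the minus strand from 13552 to 14070 and named after its values were seen, took 0.286% ± 0.0437 of counts in sham and 0.0473% ± 0.00239 in IR24h libraries (n = 3). In edgeR its log2 fold change was −2.00 ± 0.38 (adjusted p = 0.0152). The end of mt-Nd5 (11742 to 13565) overlaps mt-Nd6, and mt-Atp8, with the ratio of 14.7, overlaps mt-Atp6. Both were named after their values were seen. Whether strand and overlapping genes were counted alike in both groups is not given in the sources used here.

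**Figure D3:**
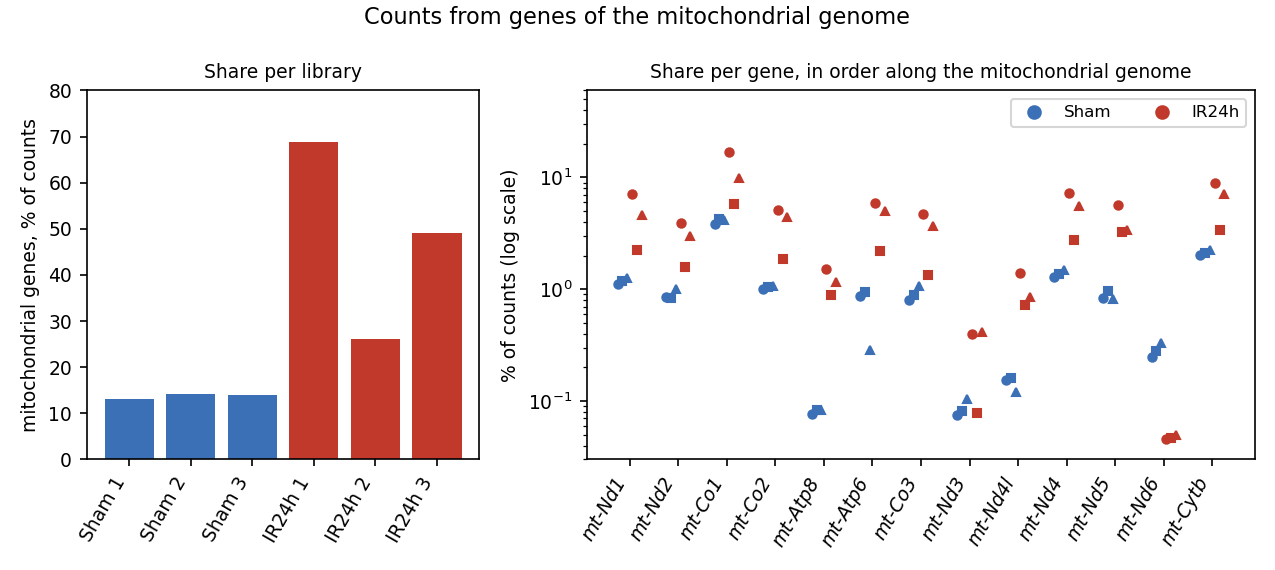
Left, percent of counts from genes of the mitochondrial genome in each library, as bars from 0. Right, the share of each of the 13 genes per library on a log scale, with blue for sham, red for IR24h and circles, squares and triangles for libraries 1, 2 and 3; mt-Nd6 alone lies lower in each IR24h library than in each sham library.

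Some strongly raised genes were neighbours on a chromosome. Of 306 called genes with a log2 fold change of at least 3, 57 lay in 10 raised stretches with 64 tested genes in all, of which 55 had under 3 CPM in sham. The stretch with the most genes, 11, spans 6227765 to 6544169 on chromosome 19 and includes Slc22a12, and among its other genes, named after their values were seen, the splicing factor Sf1 rose from 2.61 ± 0.680 to 73.1 ± 5.98 CPM and Ehd1 from 3.10 ± 0.317 to 158 ± 23.4 CPM. The 40 tested genes drawn on both sides of it had a median log2 fold change of 0.41. Whether sham reads of the raised stretches were left out stays open.

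**Figure D4:**
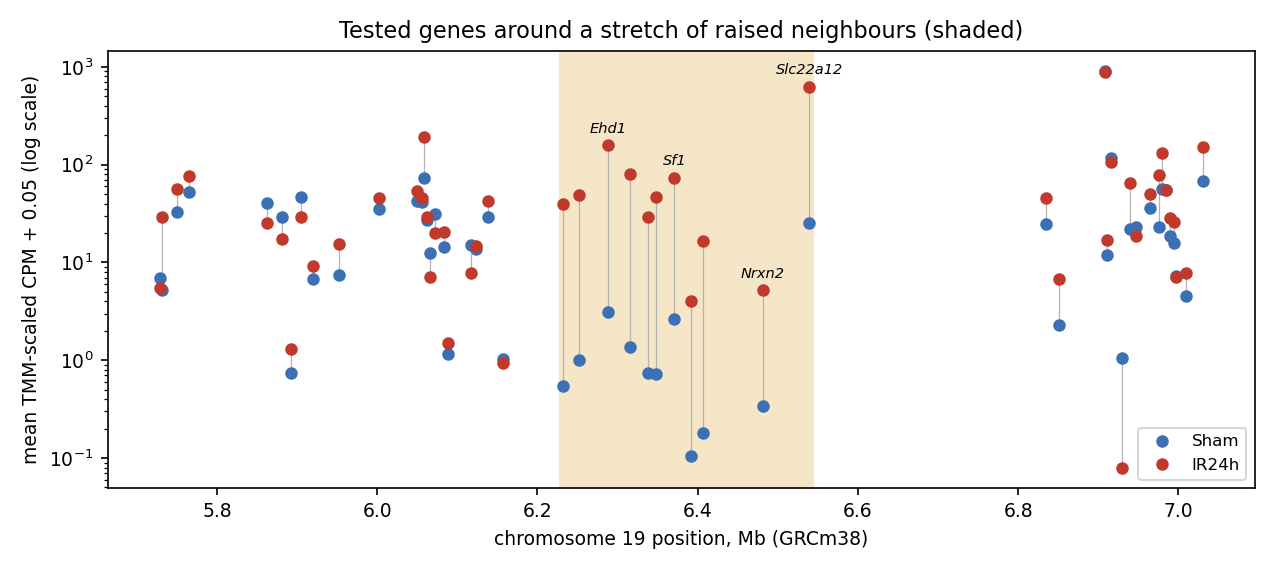
Mean TMM-scaled CPM plus 0.05 (log scale) of tested genes along chromosome 19 (GRCm38, Mb) in sham (blue) and IR24h (red), joined by a line per gene, with the stretch of raised neighbours shaded. Inside it sham means reach at most 25.4 CPM and IR24h means run from 4.02 to 629 CPM, while most genes outside it have similar means in both groups.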

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

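All tests in this part on stretches of neighbouring genes and on mitochondrial genes were chosen only after the result was seen. Those on the splits of the libraries and on IR24h library 2 were set before they were run. The tests on library 2 concern a pattern found in these data. Of 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called as many genes. It called 2214 and the highest of the others 0, but 10 splits are too few for a share under 0.05.

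Signals outside the comparison stood out. Among the 83 genes without a sham value, 9 had more than 3 counts in each IR24h library. BC005561, for example, had 101, 291 and 52 counts and Zbed6 37, 906 and 59 in IR24h libraries 1, 2 and 3. In the FPKM values, which were not themselves compared between the groups, the implied gene length differed between sham and IR24h libraries for 13.1% of the genes compared.

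Strongly raised genes sat next to each other: 57 of 306 called genes with a log2 fold change of at least 3 lay in 10 stretches. Over 1000 shuffled gene orders there were 16 at most and 2.46 on average (permutation p = 0.0010, the smallest that they can give), which argues against chance position. Shared gene families do not account for most of it, since 14 of the 57 share the first 4 characters of their symbol with another member, 7 of them S100a and Sprr genes on chromosome 3. A candidate explanation is that reads of these stretches were left out of the sham values, for instance by a reference that holds the stretch more than once. Reads outside the listed genes equal at least 7.91% of the listed counts in sham libraries. The stretches would need 0.390% of the listed counts, so there is room for it. Those reads can be of any origin, so this does not speak for the explanation, and processing and group cannot be told apart. Joint regulation of neighbours after ischemia was not tested, and without the stretches 1111 genes were higher and 1021 lower.

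The share of counts from mitochondrial genes was higher after ischemia/reperfusion. A common rise of all mitochondrial transcripts would put each of the 13 genes higher. The mean share of mt-Nd6 in IR24h was 0.165 of that in sham, below the values of all sham libraries in each IR24h library. The other genes had ratios of 2.68 to 14.7. This rests on 1 gene for which a difference in counting stays open, so it cannot decide. A step shared by all IR24h libraries would not by itself give the spread among them, an SD of 21.4 percentage points against 0.571 in sham, but whether they were prepared alike is not given in the sources used here, so differences in handling between single libraries stay open. Separate processing may account for part of the difference between the groups, since the lowest IR24h share of 26.2% lies above the highest sham share of 14.2% as a shift of each library would give, and this cannot be told apart from an effect of the injury. Strand-aware counting in 1 group is an untested possibility for mt-Nd6, which is read from the other strand than the rest.

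IR24h library 2 stood apart from IR24h libraries 1 and 3. With a gene length and GC trend removed from each library its higher correlation with them was 0.820, below the 0.85 set beforehand, which argues against that trend as the whole cause. With all 3 libraries thinned to 4008001 counts of genes outside the mitochondrial genome, it was 0.770 against 0.896 between libraries 1 and 3, which argues against depth. Fat in library 2 may play a part, with 313 counts of Adipoq there against 0 and 3, and stays open: 2.31% of tested genes were at least 4-fold lower in library 2 than in both others, between the limits set beforehand, 1.81% at least 4-fold higher, and dilution by fat was not tested. A difference in injury between the IR24h samples was not tested.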

How the results depend on the processing

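All 4 settings named as added in the account of the processing were chosen after seeing the data; the others were planned. The direction of each called named gene and called list held under every setting that gave a value. Of the 3 named genes not called, all changed direction over the settings, with log2 fold changes of −2.73 to 1.07 for Ifit3, −0.89 to 0.64 for Lck and −0.95 to 1.72 for Hba-a1. Scaling by library size alone gave 398 higher, 611 lower and 1009 genes changed at least 2-fold, with a median log2 fold change of −0.39 and 39.4% higher. DESeq2 gave 2080, 1688 and 3233, and the test with IR24h 2 as the only injured library 2690, 2749 and 3580, which include 983 of the higher and 1010 of the lower genes. Leaving out 1 library at a time gave 246 to 3297 higher, 196 to 3382 lower and 458 to 4916 genes changed at least 2-fold, lowest without a sham library and highest without IR24h 2. The log2 fold change of Isg20 was 2.28 to 3.14 over these, with a lost call without sham 1, 2 or 3 (3.00, 2.67 and 2.69). Fewer libraries leave fewer degrees of freedom. This loss is the same for a sham as for an IR24h library, so it cannot account for the difference between them. The test shares the spread of each gene over both groups. IR24h libraries agreed less with each other (r = 0.759 to 0.898) than sham libraries did (0.974 to 0.983), so the IR24h spread weighs more without a sham library. What part this had was not tested. Of 65 called named genes, 31 stayed called without each library, 34 were lost without some sham library, 16 without some IR24h library and 0 without IR24h 2. With library size as the only scaling 18 were lost, with limma-voom 6, and with any other setting 3 or fewer.

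With the replicate block there were 814 higher and 843 lower genes (793 and 751 shared with the unblocked test), and Isg20 changed by 2.64 ± 0.45 (adjusted p = 0.0153). Of the called named genes, 3 were lost with it (Hnrnpd, Exosc8 and Mcm2, adjusted p = 0.0936, 0.0557 and 0.0521), and the interferon list (lower, 0.0288) and the cell death list (higher, 0.0470) were gained. The labels give no pairing, and deviations from the group mean correlated at −0.12, 0.16 and 0.31 for libraries of equal number and at −0.32 to 0.22 for the others. Counts under RLE and upper-quartile scaling, limma-voom, the other filters, removal of mitochondrial genes, equal implied length, no raised stretches and a removed length and GC trend lay within 1.5 times those reported. Camera called 13 lists, 1 with an estimated correlation and 11 to 15 without 1 library. At this depth a count of 0 in a library leaves room for 3 counts, which are 0.176 to 0.233 CPM of the library total. At the depth and spread of these libraries together 0 of 69 genes simulated to change 2-fold were called, and neither was varied alone. That simulation changed far fewer genes than were called in the real data, so it may understate what was detectable.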

Other observations

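The test of gene families was chosen only after the result was seen, and covers 86 families of at least 15 tested members in both directions. Fisher's exact test counts genes as independent, although genes measured in the same libraries can move together. Its p-values thus do not measure the spread between libraries. For the proximal tubule list, camera gave an adjusted p of 4.39e-12 at the preset correlation and 0.228 with an estimated one. Solute carriers, the membrane transporters with symbols in Slc, were lower more often than other genes. Of 288 tested, 75 fell and 20 rose, so that 26.0% were lower against 7.22% of other genes (1-sided Fisher's exact test, adjusted p = 9.29e-20 over 172 tests). Outside the fixed lists, 59 fell and 17 rose. Slc22a22, an organic anion transporter, fell from 106 ± 4.33 to 3.54 ± 2.09 CPM (SD, n = 3), and the glucose 6-phosphate transporter Slc37a4 from 274 ± 12.6 to 28.2 ± 9.67 CPM. The cystine transporter subunit Slc7a9 fell from 176 ± 7.22 to 28.3 ± 9.35 CPM. Among those that rose, Slc34a2, a phosphate transporter, went from 2.26 ± 0.879 to 59.4 ± 39.1 CPM. With library size as the only scaling 49 fell and 8 rose, and without sham 1, 2 or 3 there were 28, 24 and 25 lower and 6, 6 and 8 higher. Without IR24h 1, 2 or 3 there were 54, 140 and 59 lower and 15, 50 and 22 higher. These genes were named after their values were seen.

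In 3 other families called genes of 1 direction were more frequent than among other genes, while some or most members were not called. Of 30 collagen genes 12 rose and 1 fell (adjusted p = 2.83e-04 for higher genes). Col3a1 rose from 23.8 to 337 CPM and Col6a3 from 11.5 to 90.3 CPM, while Col6a6 fell from 4.18 to 0.0341 CPM. Of 19 aldehyde dehydrogenase genes 8 fell and 3 rose (adjusted p = 0.00224 for lower genes), with Aldh4a1 lower at 86.5 against 588 CPM and Aldh1a2, which makes retinoic acid, higher at 23.8 against 1.90 CPM. Of 16 UDP-glucuronosyltransferase genes 6 fell and 0 rose (adjusted p = 0.0341 for lower genes), and Ugt3a2 fell from 1408 to 162 CPM. Without sham 1, 2 or 3 there were 4, 3 and 4 higher collagen genes, 2, 2 and 1 lower Aldh genes with 1 higher each time, so that no lean was left without sham 3, and 3 lower Ugt genes each time. Without IR24h 1, 2 or 3 there were 10, 17 and 11 higher collagen genes, 5, 10 and 5 lower Aldh genes with 3, 7 and 4 higher, and 5, 13 and 4 lower Ugt genes. The direction of all 4 families held under each scaling tried.

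Lower genes lay next to each other too, though fewer of them: 13 of 163 called genes with a log2 fold change of −3 or less were in such stretches. Over 1000 shuffled orders there were 9 at most. The transporters Slc22a28, Slc22a29, Slc22a30 and Slc22a8 form one of them, from 8062209 to 8611835 on chromosome 19.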
